A study of Homo sapiens with 2 samples.

How the data were processed

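Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in HCT116 cells, a human colon cancer cell line. Per the labels, 10-cm plates at 70% confluence received 10 ml of medium with either 10 µl of DMSO or 10 µM Nutlin-3A in DMSO. The duration of the treatment is not given in the sources used here. Nuclei were prepared by a published ATAC-seq protocol with repeated early steps to clean them further, and the libraries were sequenced as paired reads of 37 bp, per the labels' protocols. There was 1 library per group and therefore no replicate.

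The deposited data are 1 list of peaks for each library, called separately. Per the submitters' processing notes, MACS2 was used and the genome build was hg38. The version and settings of MACS2, the aligner, the handling of duplicates and of mitochondrial reads, and any shift of read ends for the Tn5 insertion offset are not given in the sources used here. The deposited lists carry, for every peak, a fold enrichment over the local background (a linear ratio), the −log10 of a p-value and of a q-value, and a score. These are the authors' values as MACS2 writes them. They belong to the peaks of their own list and were used here to describe, rank or filter peaks within that list, and not as measures of change between lists. The exceptions are an estimate of the background of each library and a calculation for GDF15 and PANK1 in the closing section, which takes a stacked number from a peak's fold and the genome-wide background. That calculation was first taken to favour sampling at the calling floor for GDF15; the condition that it decides nothing where it puts a called peak under the floor of its own list was added after its values were seen. The deposited score was 10 times the −log10 q, truncated to a whole number, in 99.998% of DMSO and in 100% of Nutlin-3A peaks and was not used further. The largest q was 0.0994 in the DMSO list and 0.0978 in the Nutlin-3A list. The numbers in the deposited peak names run past the number of lines, so that 368 DMSO and 254 Nutlin-3A peak numbers (0.418% and 0.397%) were missing, by a filter that is not given in the sources used here. Neither list held a peak on the mitochondrial chromosome, while 487 DMSO and 327 Nutlin-3A peaks lay on contigs other than chromosomes 1 to 22, X and Y.

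Read totals are not part of the deposited lists. The background of each library was estimated from the peak values, because MACS2 computes the fold with a pseudocount of 1 and the p-value from a Poisson distribution. The most frequent pair of fold and −log10 p in the DMSO list (3.10 and 3.64, in 11540 peaks) equalled that of 3 stacked fragments or reads over a background of 0.289. The most frequent pair in the Nutlin-3A list (3.69 and 4.46, in 2551 peaks) equalled that of 4 over a background of 0.354. The background was thus 1.23 times higher in the Nutlin-3A library. This is not a ratio of read numbers, since the background also depends on the length of the stacked fragments or reads. In the DMSO list 13123 peaks were flat stacks of 3, and the Nutlin-3A list held 0 of these. A lower stacked number could thus enter the DMSO list. Relative to the background the floors lay closer together, as the Nutlin-3A background was the higher one. The match allowed a difference of 2e-05 in −log10 p plus rounding.

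Peaks of the DMSO and Nutlin-3A lists were called shared when they overlapped by at least 1 bp. Shares are given with 95% Clopper-Pearson intervals, which cover counting error only and do not describe the spread between cultures. No p-value was computed, since 1 library per group gives no estimate of that spread. Gene positions came from a RefSeq gene table of GRCh38.p14, the same assembly as hg38, restricted to 20037 protein-coding genes. The design had foreseen windows around transcript starts. The gene table used gives neither strand nor transcripts, and a gene-end peak was therefore defined as a peak within 500 bp of either end of the annotated gene. This definition counts both ends of a gene alike and misses every promoter inside the annotated gene, main promoters included, and neither exons, introns nor UTRs were assigned.

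Before the data were examined, 15 gene lists with 442 entries were fixed, all of which matched the gene table, 1 of them through an older symbol. For each list the number of genes with a gene-end peak in the Nutlin-3A list only, minus the number in the DMSO list only, was set against 10000 random lists of the same size matched in 10 bins of the mean within-list percentile rank of these peaks. Peaks found in 1 list only within 50 kb of a gene end were counted once per gene list, and the Nutlin-3A share of them was set against 10000 random lists matched in 10 bins of the number of peaks in that range. A missing gene-end peak entered the mean rank as 0, so that the matching partly fixes how many genes with a peak in 1 list only, or in neither, a random list can hold. Unmatched random lists were an alternative for the p53 targets only. Both percentiles describe these libraries and are not tests of the treatment. Genes are named by a rule fixed before the data were examined: 10 well-known p53 targets, up to 5 genes per list and direction with a gene-end peak in 1 list only, and the genes nearest to the 10 highest peaks of each list by −log10 q and to the 10 highest found in that list only. An item that this rule selects is not reported here. The p53 motif comparison foreseen in the design was not run, because no genome sequence was used here.

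The computations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. For the comparison of the DMSO with the Nutlin-3A list, 32525 of 32525 planted overlaps were recovered among 54519 simulated peaks, with 0 wrong calls, and the overlap counts of the deposited lists were identical to those of bedtools. Of 350 simulated pairs of fold and −log10 p, 350 gave back the stacked number they were made with. For the gene ends of the 77 p53 targets, 4.95% of 2000 simulated lists without a planted change fell in the highest 5% of random lists. This share was 46.4% with 4 planted gains and 94.5% with 8. The simulated lists were drawn in the same way as the random lists, and gains were added to their net number. These shares therefore check the computation and not the matching. Alternatives to the main settings were a stricter q, equal numbers of peaks, other overlap rules, joined peaks, distal peaks, autosomes, other distances and unmatched random lists.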

Results

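Accessible chromatin was compared between HCT116 colon cancer cells given DMSO and HCT116 cells given 10 µM Nutlin-3A, with 1 ATAC-seq library per group. Nutlin-3A is known as a small molecule that occupies the p53-binding pocket of MDM2 and thereby stabilises p53, whereas the labels call it an inhibitor of p53. The comparison asks which accessible sites differ between the treated and the control culture. Because neither group was replicated, every difference given here is one between a pair of libraries, with no replicate check. All positions are in hg38, and the fold enrichments and −log10 q values are the authors' own for each peak.

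The DMSO list held 87627 peaks covering 16.6 Mb, and the Nutlin-3A list held 63754 peaks covering 16.1 Mb. The median peak width was 126 bp (interquartile range 74 to 212) in DMSO and 162 bp (101 to 311) in Nutlin-3A. The median fold enrichment was 4.16 within the DMSO list and 5.12 within the Nutlin-3A list. The DMSO list was longer on 23 of 23 chromosomes (1 to 22 and X), by 1.28 times on chromosome 17 up to 1.47 times on chromosome 13. The lists did not reach down to the same stacked number, since peaks of 3 stacked fragments were called in DMSO and the weakest flat stacks in Nutlin-3A were of 4. One filter kept only peaks with a fold above that of 4 stacked fragments over the background, 3.88 in DMSO and 3.69 in Nutlin-3A. This cut was stricter in DMSO, whose background was lower. It left 49719 DMSO and 56363 Nutlin-3A peaks, so that the order of the list sizes turned round. When only the flat stacks of 3 were left out, 74504 DMSO and 63754 Nutlin-3A peaks remained, and the order held.

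Most accessible sites of the Nutlin-3A culture were also found in the DMSO culture. Of the Nutlin-3A peaks, 52619 overlapped a DMSO peak (82.5%, 95% interval 82.2 to 82.8), and 11135 did not. In the other direction, 53749 DMSO peaks overlapped a Nutlin-3A peak (61.3%, 61.0 to 61.7), and 33878 did not. The order of these shares turned round with peaks of −log10 q of 5 or more, to 76.5% for Nutlin-3A and 83.0% for DMSO, and above 4 stacked fragments, to 73.5% and 84.4%. With equal numbers of peaks they were 79.9% and 80.6%. Both lists together covered 21.8 Mb, of which 10.8 Mb, or 49.7%, lay in both. Sharing followed the strength of the peak within its list. In the highest decile by −log10 q, 8755 of 8763 DMSO peaks and 6376 of 6376 Nutlin-3A peaks overlapped a peak of the other list. In the lowest decile these shares were 10.9% in DMSO and 40.1% in Nutlin-3A. Peaks found in 1 list only were narrow, with a median width of 73 bp in DMSO and 92 bp in Nutlin-3A, against 168 and 181 bp for shared peaks.

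**Figure D1:**
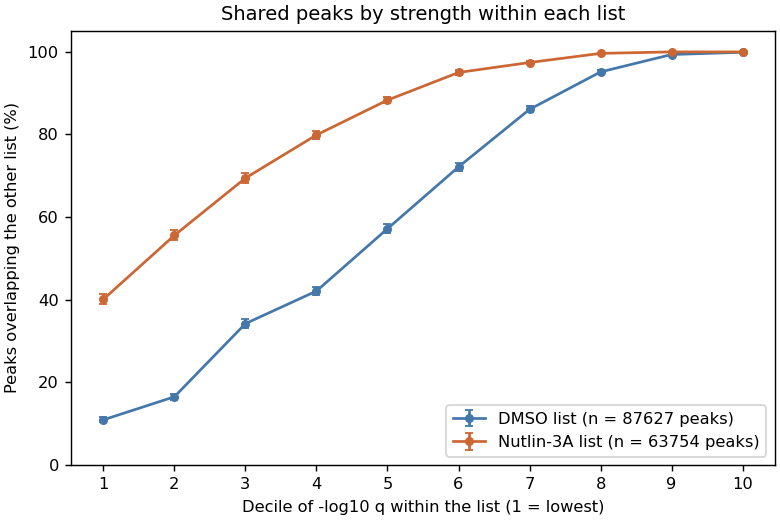
Share of peaks overlapping the other list (%, y axis) by decile of −log10 q within the list (x axis, 1 is the lowest) for the DMSO (blue) and Nutlin-3A (orange) library, with 95% Clopper-Pearson intervals that cover counting error only. The share rises from 10.9% to 99.9% in DMSO and from 40.1% to 100% in Nutlin-3A.

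Gene ends were over-represented among the shared sites. Of the shared peaks, 18.9% of those in the DMSO list (95% interval 18.6 to 19.3) and 18.8% of those in the Nutlin-3A list (18.5 to 19.2) lay within 500 bp of an end of a protein-coding gene. The figure was 3.10% (2.92 to 3.30) for DMSO-only peaks and 5.61% (5.19 to 6.05) for Nutlin-3A-only peaks, of which 57.5% and 55.6% lay outside genes. Of 20037 protein-coding genes, 10777 had a gene-end peak in both lists, 391 in the Nutlin-3A list only, 681 in the DMSO list only and 8188 in neither. Windows moved by 20 kb along the chromosome held a peak for 8.75% of genes in DMSO and 7.25% in Nutlin-3A, against 57.2% and 55.7% for the gene ends themselves. With peaks of −log10 q of 5 or more in both lists, 1123 genes had such a peak in the Nutlin-3A list only and 537 in the DMSO list only, the opposite order.

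Genes known to be activated by p53 mostly had accessible ends in both cultures. Of 77 such genes, 59 had a gene-end peak in both lists, 3 in the Nutlin-3A list only, 1 in the DMSO list only and 14 in neither. CDKN1A, FAS and BBC3 are among the 14, because their peaks lie inside the annotated gene and not at its ends. The 3 in the Nutlin-3A list only were GDF15, which encodes a stress-induced secreted factor, PANK1, a pantothenate kinase, and ORAI3, a calcium channel subunit. The GDF15 peak covered its gene end (chromosome 19, 18386067 to 18386188, fold enrichment 4.31, −log10 q 2.97), and the nearest DMSO peak was 5643 bp from an end of the gene. The PANK1 peak (chromosome 10, 89645282 to 89645530) had a fold enrichment of 3.33, and a DMSO peak lay 695 bp from the gene end. The ORAI3 peak (chromosome 16, 30948303 to 30948571) overlapped a DMSO peak that lay 581 bp from the gene end and so missed the window. PGF, encoding placental growth factor, was the gene with a peak in the DMSO list only (chromosome 14, 74955621 to 74955734, fold enrichment 3.25). The net number of 2 was reached or exceeded by 9.89% of matched random lists, whose mean was −1.67 and whose central 95% ran from −6 to 3, and by 9.42% of unmatched ones. It was 0 with windows of 1000 bp.

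The main p53 targets showed peaks at the same sites in both libraries. MDM2, which encodes the ubiquitin ligase of p53, had a peak over its gene end in DMSO (chromosome 12, 68808012 to 68808222, fold enrichment 9.55) and in Nutlin-3A (68807889 to 68808486, 5.97), and a second shared peak inside the gene (68808864 to 68809028 in DMSO). BAX, SESN1, TP53I3, BTG2 and ZMAT3 also had gene-end peaks in both lists. CDKN1A, encoding the cell cycle inhibitor p21, had a shared peak inside the gene 2114 bp from its end in DMSO (chromosome 6, 36678577 to 36678724) and a DMSO-only peak at 36680490 to 36680540. FAS, a death receptor, had 3 shared peaks inside the gene in each list, and BBC3, encoding the apoptosis regulator PUMA, had 1. Over these 10 genes and 5 kb on either side, a span chosen after the values were seen, 22 of 24 DMSO peaks and 21 of 22 Nutlin-3A peaks overlapped the other list. The Nutlin-3A exception was the GDF15 peak, and the DMSO exceptions lay in CDKN1A and ZMAT3. Within the planned 50 kb of the gene ends, 18 of 58 DMSO peaks and 7 of 46 Nutlin-3A peaks were found in that list only, with 4 of the 18 around each of CDKN1A and BBC3 and 4 of the 7 around GDF15.

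**Figure D2:**
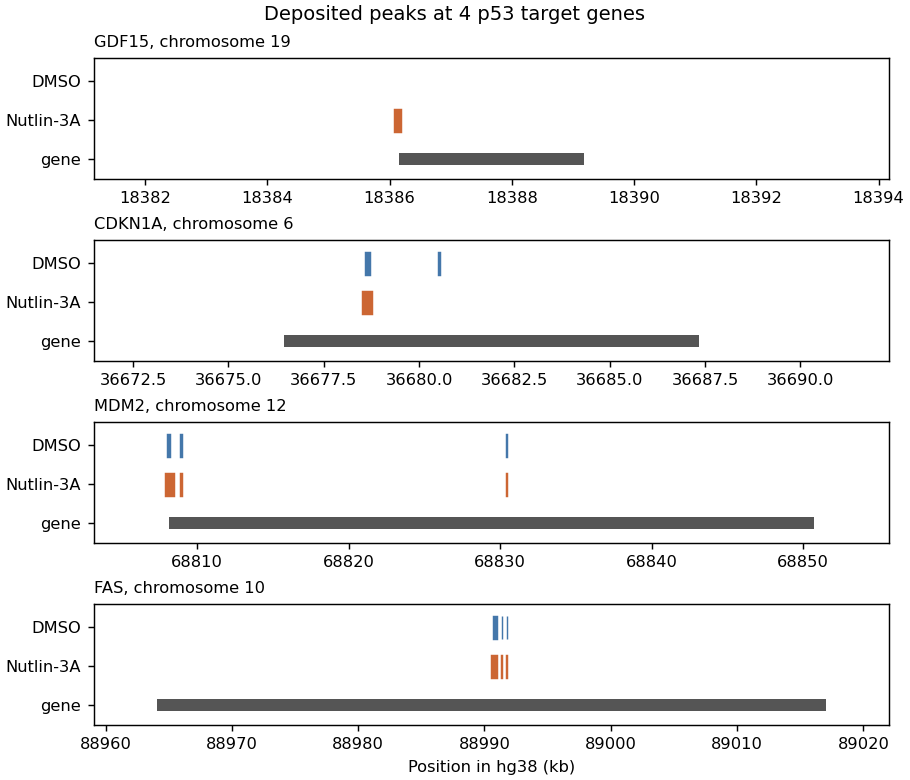
Deposited peaks of the DMSO (blue) and Nutlin-3A (orange) library at GDF15, CDKN1A, MDM2 and FAS, with the annotated gene in grey and 5 kb on either side; the x axis is the hg38 position in kb. GDF15 has a peak in the Nutlin-3A list only, while CDKN1A, MDM2 and FAS have peaks at overlapping positions in both.

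The wider surroundings of p53 targets, gene ends included, did not stand apart either. Within 50 kb of the gene ends of the 77 p53 targets, 61 peaks were found in the Nutlin-3A list only and 149 in the DMSO list only, a Nutlin-3A share of 29.0% (95% interval 23.0 to 35.7). Matched random lists had a median share of 28.3%, and 40.9% of them were as high. With peaks of −log10 q of 5 or more the share was 63.9%, and random lists then averaged 62.0%.

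Gene-end peaks in both lists were found for nearly all cell cycle genes and for 56% to 78.3% of the genes of other stress and signalling lists, against 53.8% of all protein-coding genes. Of 56 cell cycle genes known to be repressed through p53 and p21, 55 had a gene-end peak in both lists, and UHRF1 had one in neither. Of 34 immediate early genes, 26 were in both lists, with MCL1, a survival factor, in the Nutlin-3A list only (fold enrichment 3.69) and KLF2 in the DMSO list only (3.43). Of 25 interferon-stimulated genes, 14 were in both, ISG20 and OASL in the Nutlin-3A list only, and OAS1 in the DMSO list only. Of 23 NF-κB and inflammatory genes, 14 were in both and RELB in the DMSO list only. Of 23 heat shock genes, 18 were in both and HSPB1 in the DMSO list only. Of 22 Wnt targets, 13 were in both, CCND1, encoding cyclin D1, in the Nutlin-3A list only (fold enrichment 3.65) and NOTUM in the DMSO list only (3.62). Of 38 housekeeping genes, 34 were in both, TUBB in the Nutlin-3A list only, and PSMB4 and EEF2 in the DMSO list only, so that genes used by every cell also entered 1 list only. The peaks of ISG20 and RELB overlapped a peak of the other list that lay just outside the window. The MCL1 and OASL peaks both had a fold of 3.69, that of the weakest flat stacks of the Nutlin-3A list, of 4 fragments. For these 7 lists, between 22.9% and 94.4% of matched random lists had as high a net number.

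Some markers of intestinal epithelium had accessible gene ends in both cultures. Of 33 intestinal genes, 10 had a gene-end peak in both lists, among them CDX2, an intestinal transcription factor, and the epithelial adhesion genes EPCAM and CDH1, and 22 had one in neither list, among them CDX1, VIL1, KRT20 and HNF4A. This share of 30.3% lay below the 53.8% of all protein-coding genes. CLDN7 was in the Nutlin-3A list only. The count in both lists was 2 of 25 for blood, 1 of 16 for fibroblasts, 1 of 15 for endothelium, 4 of 19 for neurons, 2 of 18 for hepatocytes and 2 of 18 for muscle, and differences between the lists were not tested. SPI1 of the blood list, ROBO4 of the endothelial list, TUBB3 of the neuronal list, SERPINA1 of the hepatocyte list and ACTN2 of the muscle list were in the Nutlin-3A list only. SYN1 of the neuronal list and TNNI3 of the muscle list were in the DMSO list only. For these 6 lists with a gene in 1 list only, between 23.2% and 52.8% of matched random lists had as high a net number. The fibroblast list had none, and its comparison with random lists was void. The peaks of CLDN7, SPI1 and ROBO4 overlapped a DMSO peak just outside the window.

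**Figure D3:**
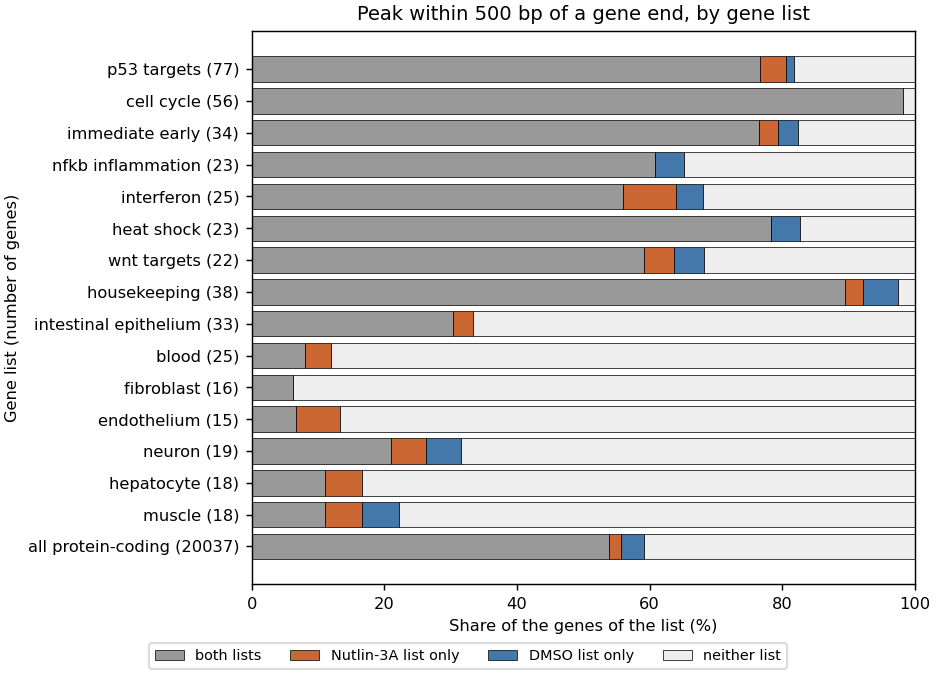
Share of the genes of each list (x axis, %) with a peak within 500 bp of a gene end in both libraries (grey), in the Nutlin-3A list only (orange), in the DMSO list only (blue) or in neither (pale), with 1 library per group and the number of genes in parentheses. The share in both lists is 76.6% for p53 targets, 98.2% for cell cycle genes and 53.8% for all protein-coding genes.

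The highest peaks of either library were shared, and 6 of the 10 highest by −log10 q were the same sites in both. In each list part of these 10 lay at gene ends. POT1 and TERF1, which encode telomere-binding proteins, OTUD6B, MSMO1 and ARRDC4 had such a peak in DMSO, and KBTBD8, MSMO1, G3BP1 and NUDCD1 in Nutlin-3A. Others lay away from gene ends, among them a 58 bp peak inside CPA6 (chromosome 8, 67585456 to 67585513) with a fold enrichment of 44.5 in DMSO and 40.3 in Nutlin-3A. The remaining sites were nearest to MYOM2, PROS1, ST6GALNAC5, FRG2 and FRG1.

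Among the sites found in DMSO only, the highest were narrow. A 54 bp peak inside ELOVL7 (chromosome 5, 60761539 to 60761592) had a fold enrichment of 36.3, and peaks of 53, 47 and 51 bp nearest to FAM98A, RBFOX2 and TLE4 had values of 29.9, 29.6 and 22.8. All of these were narrower than the narrowest peak of the Nutlin-3A list, of 55 bp. Others among the 10 highest were nearest to PLCB4, GNG12, PAXIP1, DPY19L1 and IRS1. The highest Nutlin-3A-only peaks had fold enrichments of 7.17 to 7.88 and widths of 67 to 230 bp. They were nearest to CR1L (chromosome 1, 207654491 to 207654571), SMCO1, LSAMP, NEK10, PHACTR3, GULP1, RBMS3, EDA, POU1F1 and ENTREP2, and none of these genes was in the p53 target list.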

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

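The settings with 4 stacked fragments, fold 4, stacks of 3 left out, strong peaks against a whole list, and peaks overlapping the other list left out were chosen after the data were seen; the others were planned. Of 65 alternative values, 23 stayed the same, 39 moved and 3 reversed. Only the ratio of peak numbers and the net number of p53 targets could count as reversed. A turned order of the overlap shares or of the gene counts was counted as moved or the same. The ratio of DMSO to Nutlin-3A peak numbers, 1.37, reversed to 0.927 at −log10 q of 5 or more (26574 and 28671 peaks), 0.882 above 4 stacked fragments (49719 DMSO peaks) and 0.938 at fold 4 or more (47088 DMSO peaks). It was 1.36 with peaks joined and 1.17 without stacks of 3. The shares of DMSO and of Nutlin-3A peaks overlapping the other list were 59.6% and 80.3% with 50% of the shorter peak, 48.2% and 66.2% with reciprocal 50%, 61.7% and 83.6% with peaks joined, and 56.6% and 80.3% more than 1 kb from gene ends. They were 83.0% and 76.5% at −log10 q of 5 or more, 80.6% and 79.9% with 31877 peaks in each list, 84.4% and 73.5% above 4 stacked fragments, 82.8% and 76.6% at fold 4 or more, and 70.5% and 80.7% without stacks of 3. Peaks of −log10 q of 5 or more overlapped the whole other list in 98.0% and 98.9%. Which list shared more thus depended on how weak peaks were treated. The covered bases in both lists, 49.7%, became 58.5% at −log10 q of 5, 59.2% with equal numbers and 55.0% above 4 stacked fragments. The net number of p53 targets with a gene-end peak, 2, became 0 within 1000 bp, 1 with equal numbers of peaks, 5 above 4 stacked fragments and 1 with peaks overlapping the other list left out, and was 3 at −log10 q of 5. Random lists averaged 4.50 above 4 stacked fragments, 1.27 with equal numbers and 3.32 at −log10 q of 5. The Nutlin-3A share near p53 targets, 29.0%, became 63.9% at −log10 q of 5, 50% with equal numbers and 66.4% above 4 stacked fragments. Random lists moved with it and averaged 62.0%, 52.4% and 68.1%. The cause of these changes was not tested further. Autosomes alone changed neither overlap share beyond its interval. The gene's own 5′ end and the p53 motif alternatives were not run, as strand and sequence were not used here. Flat stacks of 3 fragments were listed in DMSO and not in Nutlin-3A, so absence from a list is not absence of accessibility.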

Other observations

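The tests of explanations in this part were chosen after the results were seen, and so were the genes of the next paragraph; the random-list percentiles were planned, except the one above 4 stacked fragments.

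Over all protein-coding genes, those of the fixed lists included, some gene ends had a peak in 1 library that overlapped no peak of the other. This held for 307 genes in the Nutlin-3A list, of which those with the highest −log10 q were C1QTNF9 (chromosome 13, 24322583 to 24322701, fold enrichment 7.06), GSTP1, a glutathione transferase (chromosome 11, 67583539 to 67583791, 6.34), and MARCKSL1 (chromosome 1, 32336189 to 32336348, 6.37). The nearest DMSO peak was 4678 bp from an end of C1QTNF9, 20119 bp from GSTP1 and 15249 bp from MARCKSL1. It held for 643 genes in the DMSO list, of which those with the highest −log10 q were LRRC8C, a subunit of volume-regulated anion channels (chromosome 1, 89616060 to 89616189, 8.35), STMN4 (chromosome 8, 27258451 to 27258563, 7.14) and TNK2 (chromosome 3, 195863186 to 195863286, 6.16). The nearest Nutlin-3A peak was 16535 bp from an end of LRRC8C, 6836 bp from STMN4 and 1110 bp from TNK2. Most such peaks were weaker, as the median fold of all gene-end peaks in 1 list only was 4.13 in Nutlin-3A and 3.60 in DMSO. Around PPP1R2, 14 DMSO-only peaks and 2 Nutlin-3A-only peaks lay within 50 kb. Around ADAMTS7 there were 1 DMSO-only and 7 Nutlin-3A-only peaks. Both genes were picked from 20037 protein-coding genes, and their counts were not set against those of other genes.

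Within 50 kb of 18 hepatocyte genes, 13 peaks were found in the Nutlin-3A list only and 13 in the DMSO list only, a share of 50% that 0.3% of matched random lists reached. This was the most extreme of 15 lists, and the share was 42.9% without SERPINA1. Leaving out ALB, FGA, FGB or FGG, each alone, left 13 and 13 peaks, so not every gene added a peak of its own. Random lists were not matched for genes that lie close together, so the 0.3% holds for genes drawn singly. The Nutlin-3A share was 34.9% for cell cycle genes, 38.2% for Wnt targets and 36.8% for housekeeping genes, reached by 4.41%, 5.65% and 3.27% of random lists. It was 34.8% for immediate early, 27.8% for NF-κB, 29.3% for interferon, 24.2% for heat shock, 26.5% for intestinal, 17.1% for blood, 31.0% for fibroblast, 26.3% for endothelial, 28.8% for neuronal and 32.6% for muscle genes.

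The widest peaks, up to 14669 bp in DMSO and 13246 bp in Nutlin-3A, lay on contigs outside the assembled chromosomes or more than 100 kb from a protein-coding gene end, apart from a Nutlin-3A peak 28807 bp from TARS3. All 10 widest peaks of each list overlapped a peak of the other list, and 7 of them overlapped one of its 10 widest.

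The DMSO list was longer than the Nutlin-3A list. A difference in the calling floor stays open. Leaving out peaks not above 4 stacked fragments brought the ratio of DMSO to Nutlin-3A peaks to 0.882. The same stacked number is a stricter cut over the lower DMSO background, a fold of 3.88 against 3.69 in Nutlin-3A. It left out 37908 DMSO and 7391 Nutlin-3A peaks, and a cut that is not equal cannot decide the question. The ratio was 0.938 at fold 4 or more in both, but 1.17 when only the flat stacks of 3 were left out. A loss of accessible sites under Nutlin-3A cannot be told apart from a difference between the libraries, because each group is 1 library. Strong DMSO peaks were missing from the Nutlin-3A list 1.84 times as often as strong Nutlin-3A peaks from the DMSO list (1.96% and 1.06%). The Nutlin-3A list was shorter and held no flat stacks of 3, so this ratio decides nothing. With −log10 q of 5 or more in both lists, 83.0% of DMSO and 76.5% of Nutlin-3A peaks were shared, the opposite order.

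The 4 highest DMSO-only peaks were 47 to 54 bp wide. The narrowest peak was 44 bp in the DMSO list and 55 bp in the Nutlin-3A list. No Nutlin-3A peak was thus as narrow as these 4, and their absence from that list does not show a missing site. Of the 11 DMSO peaks with a fold of 20 or more, 54.5% were under 100 bp, as were 2 of 5 such Nutlin-3A peaks, and 11 peaks are too few to say what widths are ordinary at that fold. Of 4488 DMSO peaks with a fold from 10 to 20, 0.535% were under 100 bp, with a median width of 243 bp, and 4486 were shared, so such widths were rare at the next lower fold, a class that does not hold the 4 peaks. Ordinary accessible sites and stacks of identical or mismapped reads both stay open, the second untested without reads. Of 6 DMSO peaks under 100 bp with a fold of 20 or more, 2 were also in the Nutlin-3A list.

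GDF15, PANK1 and ORAI3 were the p53 targets with a gene-end peak in the Nutlin-3A list only. For ORAI3 the window edge may account for this, as a DMSO peak overlapping the Nutlin-3A peak lay 581 bp from the gene end. For GDF15, a stacked number of 4.83 computed from the fold and the genome-wide background would be 3.94 at the DMSO background, and a Poisson count of that mean falls under 3 in 24.7% of cases, counting error of independent fragments only. The same assumption puts the called PANK1 peak at 3.51, under the 4 of the weakest flat stacks in its own list, so it does not hold for every peak, and sampling at the calling floor stays open for both genes. An opening of p53 target gene ends by Nutlin-3A cannot be told apart from chance. As high a net number was found in 9.89% of random lists. This share was 51.6% above 4 stacked fragments, 61.1% with equal numbers of peaks and 61.8% at −log10 q of 5. In simulated lists 4 added gains were picked up in 46.4% of cases. Those gains were added to the net number of lists drawn in the same way as the random lists. The 46.4% therefore does not tell how often a real opening would be found.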
